A study of Homo sapiens with 24 samples.

How the data were processed

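RNA of 24 cultures of TeloHAEC, an established endothelial line, was sequenced. The cells carried a CRISPR interference system induced with doxycycline at 2 ug/ml for 5 days, per the labels' protocols. Per the same protocols, cells of the flow experiment were lysed in Trizol before column purification, cells of the nucleofection experiment were purified on columns with DNase treatment, and poly(A) libraries were made with the NEBNext Ultra II kit. The 24 libraries formed 12 groups of 2, and the 2 libraries of a group carried different guides against the same target.

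The deposited values were TPM, 1 column per library, for 35587 gene symbols. Per the submitters' processing notes, reads were quantified with kallisto and hg38 was the genome. The version of kallisto, the transcript annotation and the way transcripts were summed to symbols are not given in the sources used here. Column sums ran from 967763 to 977560, below 1000000, so transcripts outside the table held the rest. TPM give no depth, so neither counting intervals nor floors were computed, and the precision of each value was judged from the spread between the libraries of a group. All 24 columns were matched to their samples by the guide, the condition and the index in their names, and 0 columns were left over. Nothing was left out of the main results.

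TPM were transformed to log2(TPM + 1), with a pseudocount of 1. Genes with a TPM of at least 1 in at least 2 libraries of an experiment were tested, 13920 in the flow experiment and 13529 in the nucleofection experiment. Each experiment was fitted apart with limma 3.58.1 in R 4.3.3 as a linear model with its 6 groups, with an intensity trend and robust empirical Bayes moderation, so all groups of an experiment shared 1 estimate of the spread. P values were two-sided and adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Log2 fold changes come from that model, while means ± SD are of TPM over the 2 libraries of a group. The comparisons were flow against static culture with each target's guides, each target against control guides in static culture, under flow and with control nucleofection, CCM2 against TLNRD1 guides in static culture, MAP3K3 against non-targeting nucleofection with each target's guides, and the interactions of each target with flow and with MAP3K3 guides. Groups of 2 allow no count of other splits of the samples.

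The design, the alternatives, the gene lists and the rule for naming genes were chosen before the data were examined. Named were CCM2, TLNRD1 and MAP3K3 in every comparison, KLF2 and KLF4 in every comparison, and up to 10 genes with the highest and 10 with the lowest log2 fold change among those past the threshold whose groups did not overlap and whose mean was at least 5 TPM in the higher group. For each list discussed, up to 4 members past the threshold with the largest change were named, or, where 0 passed, up to 2 with the highest mean. MESD and CFAP161 in static culture and the other neighbours of the targets were also named for their position, after their values were seen.

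The 33 gene lists held 373 genes, of which 372 were in the table. They covered flow-responsive genes, genes raised after CCM complex loss, signalling pathways, endothelial subtypes, stress and metabolic responses, and markers of other cell types. Lists could share genes. KLF2, KLF4, NOS3, THBD and AQP1 were in both the laminar-flow-induced list and the list raised after CCM complex loss. Results of these lists are therefore not independent of each other in any comparison. Each list was tested with camera (limma) with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. List members were also adjusted over the list alone. Directional tests of gene signatures used signed fry, whose p asks whether the genes of a set move on balance one way and does not compare them with other genes. It was adjusted over the 6 signatures in the text and left unadjusted where alternatives were compared. The signatures of CCM2 and TLNRD1 after nucleofection, tested in static culture, were added after the data were seen.

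Correlations of fold changes between comparisons that share control libraries were set beside 100 simulations of unchanged groups against the same controls, with the covariance of each. Guide sequences from the labels were matched to annotated transcripts of GRCh38 (GENCODE), on both strands, with and without their first base, and the adjoining PAM was read from the transcript. Only transcripts were searched, so sites in introns or upstream of genes were not looked for.

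The fits were tested on simulated data made from the real genes' means and spreads, with 200 changed genes. The changed genes were drawn only from those with a mean above about 5 TPM. Each simulated gene had the same spread in all libraries. Across real genes, B6 under flow deviated from the other flow libraries with an SD of 0.815, where the other 11 libraries had 0.317 to 0.371. So the rates given here do not describe comparisons that hold that library. For the flow comparison in control-guide cells 54% of 2-fold and 100% of 4-fold changes were recovered among 13920 genes, and for CCM2 guides with control nucleofection 89% and 99% among 13529 genes, with 4.9% and 5.1% false calls. Over all 9 simulated comparisons, those without B6 under flow included, false calls ran from 4.7% (CCM2 by MAP3K3) to 7.9% (CCM2 by flow), with 7.1% for CCM2 guides in static culture and 6.5% for MAP3K3 guides in control-guide cells. Of 50 simulated lists of 20 genes moved by 0.7 on the log2 scale, camera and fry each called all 50, and they called 2 and 3 of 50 unmoved lists. The simulated genes varied independently, so these lists cannot show how often correlated lists are falsely called. In the flow experiment the estimated correlation of the mitochondrially encoded genes was 0.995.

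The alternatives were a pseudocount of 0.1, no filter on low values, quantile normalization, median-ratio scaling, 1 fit of all 24 libraries, the guide as a replicate block, and each library left out in turn, in which case the remaining library of the group was assumed to vary like the other groups. The others were added after the data were seen: leaving out the library of guide B6 under flow, quality weights (limma's arrayWeights), and the replicate block with that library left out. In groups of 2 the quality weights are equal for both libraries (0.172 for each control library under flow), so they weight groups and cannot single out 1 library. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, statsmodels 0.14.6 and matplotlib 3.10.9, and statmod 1.5.0 was used with limma.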

Results

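The transcriptomes of 24 cultures of TeloHAEC, a telomerase-immortalised line of human aortic endothelial cells, were measured by bulk poly(A) RNA sequencing. The cells carried doxycycline-inducible KRAB-dCas9, which silences a gene at its promoter (CRISPR interference), and 1 of 6 guide RNAs. Guides F6 and C2 targeted CCM2, a scaffold protein of the cerebral cavernous malformation (CCM) complex. Guides B3 and D12 targeted TLNRD1 (MESDC1 in the labels), a talin rod domain protein, and B6 and D2 were non-targeting controls. In the flow experiment the cells were kept static or under laminar flow at 12 dyn/cm2 for 48 h. In the nucleofection experiment Cas9 was introduced with non-targeting guides or with guides against MAP3K3, the kinase MEKK3 that the CCM complex restrains, and RNA was taken 48 h later. Each of the 12 groups held 2 libraries, made with 2 different guides, so every mean ± SD has n = 2. The values were TPM, transcript abundances corrected for transcript length and library size, for 35587 gene symbols. Their sum per library lay between 967763 and 977560. TPM carry no read depth, so the depth behind each value is unknown and no counting interval was given. The series title places the work among efforts to link genes at coronary artery disease loci to endothelial programs.

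The guides were placed on annotated transcripts of GRCh38. B3 (GTGGCTGCGCCGCCGCCCGCA) matched the minus strand of chromosome 15 at 81001026 to 81001046 and D12 (GCCTCCGGCAGCCCCTGCGGG) the plus strand at 81001011 to 81001031. Both lay in the 5' UTR of the single exon of TLNRD1 (chromosome 15, 81000944 to 81005788), beside the PAM sequences GGG and CGG. F6 matched without its first base (AGCCGCTACATGCTCGACCC) on the minus strand of chromosome 7 at 45000256 to 45000275, in exon 1 of CCM2 (44999475 to 45076469), with the PAM GGG. C2 (GGCAAGAAGGTGAGCGTGCG) had no contiguous match in a transcript. Its first 9 bases equalled the last 9 of CCM2 exon 1 (45000355 to 45000363), and whether it runs on into the intron was not tested, since introns were not searched. B6 and D2 matched 0 transcripts. MAP3K3 lies on chromosome 17 (63622415 to 63696303), KLF2 on chromosome 19 (16324817 to 16327874) and KLF4 on chromosome 9 (107484852 to 107490482).

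Both targeted genes were lower in every library with their own guides than in every control library of the same condition. In static culture CCM2 stood at 16.1 ± 7.90 TPM with its guides and 47.8 ± 2.87 TPM with control guides, and under flow at 17.8 ± 7.59 and 89.3 ± 56.7 TPM. With control nucleofection CCM2 fell from 64.5 ± 2.54 to 18.0 ± 1.08 TPM (log2 fold change -1.79, limma adjusted p = 0.000737), while the static and flow differences did not pass (-1.60, adjusted p = 0.416, and -2.17, adjusted p = 0.395). Without the library of guide B6 under flow, which held 129 TPM of CCM2, the flow difference was -1.48 (adjusted p = 0.726). TLNRD1 fell from 47.3 ± 4.91 to 6.55 ± 2.03 TPM in static culture (-2.70, adjusted p = 0.0015), from 42.2 ± 1.15 to 5.28 ± 0.805 TPM under flow (-2.79, adjusted p = 0.00112) and from 36.9 ± 0.288 to 3.99 ± 0.599 TPM with control nucleofection (-2.93, adjusted p = 8.87e-06). MAP3K3 was at 47.3 ± 7.50 TPM with its guides and 48.8 ± 4.84 TPM without them in control-guide cells (-0.05, adjusted p = 1). The corresponding log2 differences in MAP3K3 were -0.11 (adjusted p = 0.87) in CCM2-guide cells and -0.12 (adjusted p = 1) in TLNRD1-guide cells. Cas9 cuts DNA and need not change the amount of a transcript, so these values do not check the MAP3K3 labels.

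The 3 genes were also followed in other comparisons. None of the following differences passed with all libraries or without B6 under flow, and with all libraries the smallest adjusted p was 0.297 for CCM2, 0.129 for TLNRD1 and 0.497 for MAP3K3. With CCM2 guides TLNRD1 differed from control-guide cells by 0.23 in static culture, -0.12 under flow and 0.56 with control nucleofection. With TLNRD1 guides CCM2 differed by 0.16, -0.52 and 0.02 in the same conditions. MAP3K3 differed by -0.08, -0.07 and 0.07 with CCM2 guides and by -0.10, 0.00269 and 0.03 with TLNRD1 guides, and by 0.02 between CCM2 and TLNRD1 guides in static culture. With flow in control-guide, CCM2-guide and TLNRD1-guide cells the differences were 0.73, 0.16 and 0.04 for CCM2, -0.155, -0.50 and -0.25 for TLNRD1 and -0.13, -0.12 and -0.03 for MAP3K3. The interactions of CCM2 and TLNRD1 guides with flow were -0.57 and -0.685 for CCM2, -0.35 and -0.09 for TLNRD1 and 0.02 and 0.10 for MAP3K3. Without B6 under flow, CCM2 differed by 0.04 with flow in control-guide cells and by 0.17 with TLNRD1 guides under flow, and its interactions were 0.12 and 0.00304. With MAP3K3 guides in control-guide, CCM2-guide and TLNRD1-guide cells CCM2 differed by -0.19, -0.01 and -0.09 and TLNRD1 by -0.18, -0.52 and -0.21. The interactions of CCM2 and TLNRD1 guides with MAP3K3 guides were 0.175 and 0.10 for CCM2, -0.34 and -0.04 for TLNRD1 and -0.06 and -0.08 for MAP3K3.

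**Figure D1:**
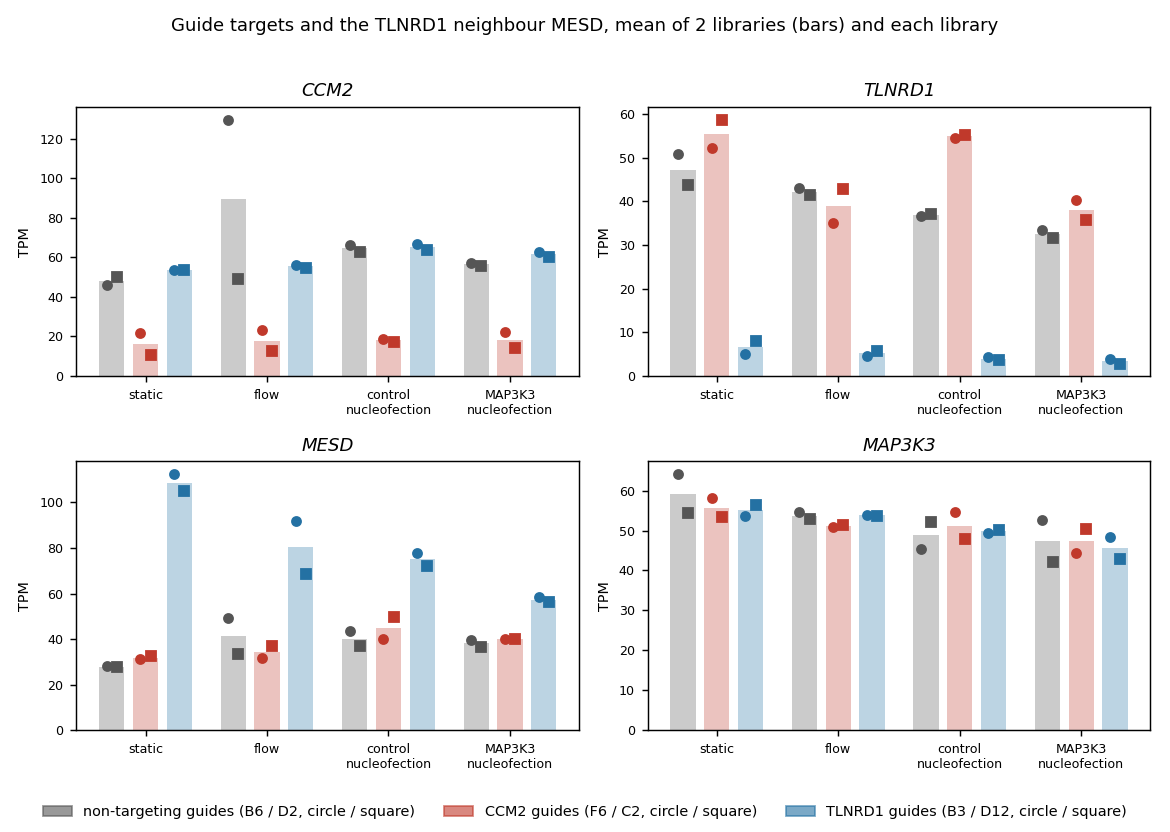
TPM of CCM2, TLNRD1, MESD (the neighbour of TLNRD1) and MAP3K3 in each of the 24 libraries (circles and squares for the 2 guides of a target), with bars at the mean of the 2 libraries of each group, by condition and guide target. CCM2 averaged 18.0 TPM with its guides and 64.5 TPM with control guides after control nucleofection, MESD 109 and 27.8 TPM with TLNRD1 and control guides in static culture, and MAP3K3 47.3 and 48.8 TPM with and without MAP3K3 guides in control-guide cells.

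The library with non-targeting guide B6 under flow stood apart from the other 11 of its experiment. Its correlations with them across genes, on the log2 scale, were 0.903 to 0.931, whereas the others correlated with each other at 0.956 to 0.984. The mitochondrially encoded genes held 1.81% of its TPM and 10.1% to 13.3% in the others, and its 10 most abundant genes held 7.66% against 10.6% to 12.7%. The same library showed 129 TPM of CCM2 and is the source of the wide SD of CCM2 under flow. In the nucleofection experiment all pairs correlated at 0.969 to 0.984, and mitochondrial shares ran from 4.46% to 9.82%. Every flow result was therefore also computed without that library, a choice made after the data were seen.

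Laminar flow changed genes of BMP signalling, the oxidative stress response and lymphatic markers in control-guide cells. The BMP target genes ID1 and ID3 rose from 82.7 ± 6.12 to 429 ± 114 TPM (log2 fold change 2.34, adjusted p = 0.00211) and from 36.5 ± 8.69 to 191 ± 55.7 TPM (2.34, adjusted p = 0.00247). SMAD6, an inhibitor in that pathway, rose by 3.48 and ATOH8, a flow-responsive transcription factor, by 2.90. HMOX1 (heme oxygenase) rose from 12.7 ± 1.46 to 108 ± 34.7 TPM, and the other targets of the redox transcription factor NRF2 that rose included OSGIN1 (2.26), TXNRD1 (1.88), SLC7A11 (1.55) and NQO1 (1.33). The Notch ligand JAG2 rose by 4.00, while the ligand DLL4 fell by 2.03 and the Notch target HES1 fell by 1.83.

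Among the genes with the largest changes, FCN3 (the lectin ficolin-3) rose from 0.364 ± 0.0778 to 29.2 ± 5.20 TPM, and LCN10, CLEC3B and ANKRD1, a target of YAP, rose by 4.10, 3.59 and 3.94. The retinaldehyde reductase gene DHRS3 fell from 9.16 ± 0.786 to 0.185 ± 0.171 TPM. SEMA3A, a repulsive guidance cue, fell by 2.74, the matrix protein tenascin (TNC) by 2.67, BAALC by 2.66, STC1 by 2.63 and SERPIND1 by 2.75. The lymphatic markers LYVE1 and PDPN fell by 2.48 and 1.26. The shear-responsive transcription factor KLF4 rose from 17.9 ± 5.98 to 47.7 ± 6.25 TPM (1.40, adjusted p = 0.014), whereas KLF2 stood at 179 ± 27.3 and 191 ± 0.868 TPM (0.10, adjusted p = 0.73). THBD (thrombomodulin) rose by 0.95, VWF by 1.32, the adhesion molecules SELE and ICAM1 by 2.00 and 1.01, and the vasodilator peptide gene ADM fell by 1.85. SELE, ICAM1 and ADM belong to the laminar-flow-repressed list. With all libraries that list was not called with flow in cells with any target's guides. RNA5SP389, RNA5SP199, RNA5SP298, RNA5SP385, AC091849.1, AC060780.3, AC114501.1, TRGV5 and MICOS10-NBL1 also passed, but these pseudogenes, clone-named genes and overlapping genes may share reads with others and are uncertain.

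In control-guide cells 968 genes rose and 380 fell with flow, of 13920 tested (limma, adjusted p under 0.05), and 4202 had an unadjusted p under 0.05. Of the 11 NRF2 targets tested 8 rose, as many as when adjusted over the list alone, and all 11 were positive (median 1.21, camera adjusted p = 3.83e-07, but adjusted p = 0.274 with an estimated correlation). Of 11 genes of the BMP and TGF-beta response 6 rose (7 adjusted over the list alone; median 1.38, adjusted p = 0.00159, and adjusted p = 0.287 with an estimated correlation). Of 14 laminar-flow-induced genes 5 rose (7 higher and 1 lower adjusted over the list alone; median 1.01, adjusted p = 0.0235, and adjusted p = 0.705 with an estimated correlation). Both lymphatic genes fell, as they did adjusted over the list alone (median -1.87, adjusted p = 0.006, and adjusted p = 0.274 with an estimated correlation), and 2 of 21 cell cycle genes fell, BUB1 and MKI67 (4 adjusted over the list alone; median -0.41, adjusted p = 0.006, and adjusted p = 0.757 with an estimated correlation). Of 12 Notch pathway genes 2 rose and 2 fell, as many as adjusted over the list alone, and the list was not called (median 0.08, adjusted p = 0.61, and adjusted p = 0.757 with an estimated correlation). The 11 mitochondrially encoded genes had a median of -1.25, none called (0 higher, 0 lower), and the low mitochondrial share of the B6 library entered this value. Without that library their median was 0.24, all 11 were positive and 2 rose (3 adjusted over the list alone; adjusted p = 0.02, and adjusted p = 0.636 with an estimated correlation), and in all 869 genes rose and 384 fell. The count was 100 without the static library of guide D2, 224 without the static library of B6, 884 without either CCM2 library under flow and 6154 without the flow library of D2, and quantile normalization gave 661 higher and 505 lower genes while median-ratio scaling gave 743 and 500. Weighting by quality, which gave both control libraries under flow the same weight of 0.172 and so did not single out B6, left 17 genes. Of the 69 named genes called 20 passed in all 12 cases with 1 library left out. Quantile normalization moved the median log2 difference of all genes from 0.10 to -0.022.

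**Figure D2:**
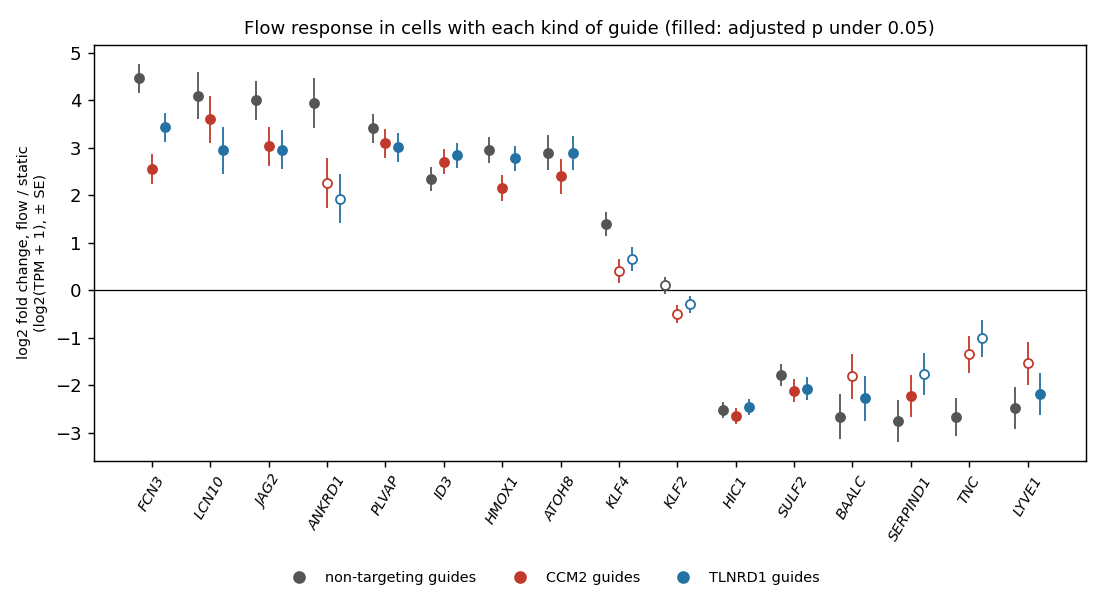
Log2 fold changes of log2(TPM + 1), flow against static culture, for 16 named genes in cells with control, CCM2 and TLNRD1 guides, with error bars of 1 standard error and filled points for an adjusted p under 0.05. ID3 changed by 2.34, 2.71 and 2.84, and KLF4 passed in control-guide cells (1.40) but not with CCM2 (0.41) or TLNRD1 guides (0.66).

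Flow was next compared with static culture in cells with CCM2 or TLNRD1 guides. In CCM2-guide cells PLVAP, a component of endothelial diaphragms, rose from 1.604 ± 0.646 to 20.9 ± 0.277 TPM, NID2, a basement membrane protein, from 26.9 ± 3.56 to 150 ± 5.98 TPM, and TM4SF18 from 11.4 ± 1.44 to 78.3 ± 0.155 TPM. ID3 rose by 2.71, JAG2 by 3.03, FCN3 by 2.55, LCN10 by 3.60, the collagen COL8A1 by 2.32 and HMOX1 by 2.16. The transcriptional repressor HIC1 fell from 48.5 ± 9.40 to 6.88 ± 0.142 TPM, the sulfatase SULF2 by 2.11, HOXA3 by 2.13, TCF15 by 1.88 and IGFBP6 by 1.85, and DHRS3, at 9.57 ± 2.21 TPM in static culture, was listed at 0 under flow. In TLNRD1-guide cells FCN3 rose by 3.43, PLVAP by 3.01, JAG2 by 2.96, LCN10 by 2.94, ATOH8 by 2.89, ID3 by 2.84 and HMOX1 by 2.78. In the same cells DHRS3 fell by 3.22, C7orf61 by 2.66, HIC1 by 2.46, the transglutaminase TGM2 by 2.39, LYVE1 by 2.18, SULF2 by 2.07, the cytokine genes CSF3 and IL33 by 2.06 and 2.02, and BAALC by 2.27. AC000041.1, AC010332.1, RNA5SP301, RNA5SP385, RNA5SP383 and the pseudogene NMRAL2P are uncertain for the reason given above.

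With flow 174 genes rose and 63 fell in CCM2-guide cells (2020 with unadjusted p under 0.05), and 333 rose and 76 fell in TLNRD1-guide cells (2404). Of the CCM2-guide calls 158 of the higher and 52 of the lower genes were also called in control-guide cells, where independent lists would share 12.1 and 1.72. For TLNRD1-guide cells 268 and 67 were shared, against 23.2 and 2.08 for independent lists. NRF2 targets rose in 8 of 11 cases in each background (8 and 9 adjusted over the list alone; medians 1.36 and 1.32, adjusted p = 8.71e-12 and 2.9e-12, but adjusted p = 0.143 and 0.105 with an estimated correlation). Of the 11 BMP and TGF-beta response genes 3 rose with CCM2 guides and 5 with TLNRD1 guides (8 and 7 adjusted over the list alone; medians 0.89 and 0.93, adjusted p = 5.12e-06 and 8e-05, and adjusted p = 0.159 and 0.216 with an estimated correlation). KLF2 differed by -0.50 (adjusted p = 0.236) and -0.30 (adjusted p = 0.461) and KLF4 by 0.41 (adjusted p = 0.519) and 0.66 (adjusted p = 0.21). Without B6 under flow the counts were 935 higher and 428 lower genes in CCM2-guide cells, and 1445 and 474 in TLNRD1-guide cells. Leaving out any 1 of the 12 libraries moved both counts by over 1.5 times, from 13 without CCM2 guide C2 under flow to 1363 without B6 under flow, and from 40 without the static library of TLNRD1 guide D12 to 1929 without D2 under flow. Of the named genes called, 10 of 35 with CCM2 guides and 15 of 40 with TLNRD1 guides passed in all 12 cases. Quantile normalization gave 123 higher and 86 lower genes with CCM2 guides and 195 and 110 with TLNRD1 guides, and median-ratio scaling gave 144 and 85, and 225 and 123.

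The difference in the flow effect between guides was tested as an interaction. Only RNA5SP385, an uncertain 5S rRNA pseudogene, passed in either case, with a difference of 3.09 for CCM2 (adjusted p = 0.0491) and 6.19 for TLNRD1 (adjusted p = 9.06e-05). KLF4 differed by -0.99 (adjusted p = 0.781) and -0.74 (adjusted p = 0.809), and KLF2 by -0.60 (adjusted p = 0.781) and -0.40 (adjusted p = 0.809). The unadjusted p was under 0.05 for 582 and 564 genes. On simulated data for this CCM2 interaction 9% of genes with a 2-fold and 84% with a 4-fold difference were recovered. Those data gave all libraries the same spread for a gene, so they held no library like B6 under flow. Without D2 under flow, where B6 was the remaining control, 3457 and 3247 genes passed. The CCM2 count was 2 without B6 under flow and 0 without CCM2 guide C2 under flow, with 460 genes at an unadjusted p under 0.05, or without any 1 of 7 other libraries, and the TLNRD1 count was 2 without the static library of CCM2 guide F6.

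CCM2 guides in static culture were compared with control guides, for the effect of CCM2 knockdown without flow. With all libraries, 0 genes rose and 2 fell, AC000041.1 and RNA5SP385, both uncertain and both listed at 0 with CCM2 guides (limma, 829 genes with unadjusted p under 0.05). KLF2 stood at 317 ± 7.75 TPM with CCM2 guides and 179 ± 27.3 TPM with control guides (log2 difference 0.83, adjusted p = 0.218), and KLF4 at 48.7 ± 0.744 and 17.9 ± 5.98 TPM (1.43, adjusted p = 0.107). Leaving out B6 under flow, a library of neither group that entered through the shared estimate of the spread, gave 125 higher and 24 lower genes from the same static libraries. In that fit KLF4 (1.43, adjusted p = 0.0289), NOS3, the endothelial nitric oxide synthase (145 ± 17.5 to 282 ± 15.0 TPM, adjusted p = 0.0247), THBD (181 ± 55.4 to 423 ± 16.7 TPM, adjusted p = 0.0228) and HEG1, the receptor that binds the CCM complex (63.0 ± 14.8 to 141 ± 8.43 TPM, adjusted p = 0.0204), were higher. SNAI2 and TAGLN were higher by 1.74 and 1.30, the protease ADAMTS1 by 1.27, and MAPK7 (ERK5, the MAP kinase downstream of MEKK3) by 0.82. SNAI2 and TAGLN are members of the mesenchymal transition list, which was called in no comparison with all libraries. CLEC3B, the prostaglandin transporter SLCO2A1, FCRLB, ABI3BP, KCNN4, the water channel AQP3 and IGFBP6 were higher by between 1.79 and 2.98. The chemokine CCL2 fell by 1.17, ID3 by 1.09, CHST15 by 1.05 and TFPI2 by 1.89.

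Of 14 laminar-flow-induced genes 0 passed over all genes tested with all libraries, 8 were higher adjusted over the list alone, and 12 were positive (median 0.92, camera adjusted p = 5.78e-13, but adjusted p = 0.138 with an estimated correlation). Of 10 genes raised after CCM complex loss 0 passed, 6 were higher adjusted over the list alone and 9 were positive (median 0.90, adjusted p = 5.73e-12, and adjusted p = 0.138 with an estimated correlation). KLF2, KLF4, NOS3, THBD and AQP1 belong to both lists, so these results overlap. The 11 laminar-flow-repressed genes had a median of -0.65 (0 passed, 1 lower adjusted over the list alone; adjusted p = 0.00519, and adjusted p = 0.138 with an estimated correlation), and the 7 arterial genes a median of -0.36, all negative (0 passed in either way; adjusted p = 0.00808, and adjusted p = 0.139 with an estimated correlation). Flow itself did not give a call of the laminar-flow-repressed list, and its members SELE and ICAM1 rose with flow in control-guide cells while ADM fell. A fall of this list is therefore not an effect that flow showed here. The count of genes was 149 without B6 under flow, 147 without D2 under flow, 14 without the static library of B6, and 0 without the static library of CCM2 guide C2 (575 at unadjusted p under 0.05) or of guide D2 (488). With the B6 flow library left out, simulated 2-fold changes were recovered in 94% of cases for this comparison, against 61% with all libraries.

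TLNRD1 guides in static culture raised MESD, the gene beside TLNRD1 that encodes a chaperone of LDL receptor family proteins, from 27.8 ± 0.260 to 109 ± 5.21 TPM (1.93, adjusted p = 0.0161). TLNRD1 itself fell, and so did the uncertain RNA5SP385. MESD lies on the minus strand at 80946289 to 80989878 of chromosome 15, with 11065 bases between it and TLNRD1. CFAP161, on the plus strand at 81007033 to 81149175, stood at 22.1 ± 0.739 TPM with TLNRD1 guides and 5.96 ± 1.39 TPM with control guides (1.74, adjusted p = 0.529). KLF2 stood at 251 ± 8.07 TPM (0.49, adjusted p = 1) and KLF4 at 30.1 ± 5.27 TPM (0.75, adjusted p = 1). In all 1 gene rose and 2 fell, and 441 had an unadjusted p under 0.05. The 14 laminar-flow-induced genes had a median of 0.54 (0 passed, 2 higher adjusted over the list alone; adjusted p = 7.89e-09, but adjusted p = 0.256 with an estimated correlation), and the 10 genes raised after CCM complex loss a median of 0.45 (0 passed, 5 higher adjusted over the list alone; adjusted p = 3.1e-07, and adjusted p = 0.256 with an estimated correlation). The 16 cholesterol synthesis genes were all negative (median -0.18, 0 passed in either way; adjusted p = 0.0116, and adjusted p = 0.808 with an estimated correlation). The count was 6 without either control library under flow and 0 without the static library of B6 (416 at unadjusted p under 0.05). MESD passed in 4 of the 12 cases with 1 library left out and TLNRD1 in 11.

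**Figure D3:**
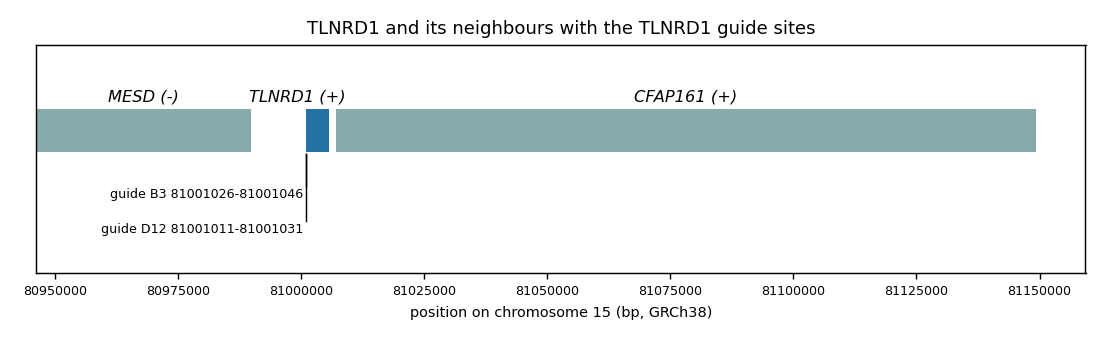
Map of chromosome 15 (GRCh38, position in base pairs) with TLNRD1, its neighbours MESD and CFAP161 (boxes from gene start to end, strand in brackets) and the sites of guides B3 and D12 (vertical lines). MESD starts 11066 bases from TLNRD1 on the other strand, and CFAP161 begins 1244 bases past its end.

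Under flow, TLNRD1 guides lowered TLNRD1 and RNA5SP298 and raised RNA5SP385, while CCM2 guides raised AC010332.1 and RNA5SP301 and lowered RNA5SP298; all but TLNRD1 are uncertain. KLF2 differed by 0.23 with CCM2 guides (adjusted p = 0.51) and 0.10 with TLNRD1 guides (adjusted p = 0.816), and KLF4 by 0.44 (adjusted p = 0.417) and 0.01 (adjusted p = 0.995). Of the 10 genes raised after CCM complex loss 0 passed with CCM2 guides, 4 were higher adjusted over the list alone and 9 were positive (median 0.46, camera adjusted p = 0.00206, but adjusted p = 0.639 with an estimated correlation). The 11 mitochondrially encoded genes were all positive with either target (medians 1.53 and 1.43, 0 passed in either way; adjusted p = 0.000182 and 0.000591, and adjusted p = 0.639 and 0.937 with an estimated correlation), set against controls that held the B6 library with 1.81% of TPM in these genes. Without that library their medians were 0.01 with CCM2 guides, 8 of 11 positive, and -0.12 with TLNRD1 guides, all 11 negative (0 passed in either way; adjusted p = 0.699 and 0.00672, and adjusted p = 0.911 and 0.8 with an estimated correlation). So the higher values depend on that library. An unadjusted p under 0.05 was found for 1741 and 1198 genes. Without D2 under flow the counts were 5174 and 4827, without either static CCM2 library 5 and 5. The CCM2 count was 1 without guide F6 under flow, and 0 without guide C2 under flow (899 genes at unadjusted p under 0.05) or without B6 under flow (794).

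CCM2 and TLNRD1 guides were also compared directly in static culture. TLNRD1 was higher with CCM2 guides (2.93, adjusted p = 0.00145), MESD was lower (-1.74, adjusted p = 0.0391) and so was the uncertain AC000041.1, which was listed at 0. KLF2 differed by 0.34 (adjusted p = 1), KLF4 by 0.69 (adjusted p = 1) and CCM2 by -1.76 (adjusted p = 1). The 10 genes raised after CCM complex loss were all positive (median 0.35, 0 passed in either way; adjusted p = 1.65e-05, but adjusted p = 0.278 with an estimated correlation), and the 20 actin cytoskeleton genes had a median of 0.20 (0 passed, 1 higher adjusted over the list alone; adjusted p = 0.000218, and adjusted p = 0.278 with an estimated correlation). An unadjusted p under 0.05 was found for 341 genes. The count of 3 genes became 0 without the static library of CCM2 guide C2 (313 at unadjusted p under 0.05), and 1 without the static library of B6 or of TLNRD1 guide B3, or without either TLNRD1 library under flow.

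With control nucleofection, CCM2 guides raised several genes of the laminar-flow-induced list, whose call was lost with an estimated correlation. In the flow experiment itself KLF2 did not pass with flow in control-guide cells. AQP1 stood there at 43.52 (D2) and 99.85 TPM (B6) in static culture and at 67.23 (D2) and 40.51 TPM (B6) under flow. PI16, a peptidase inhibitor, rose from 2.47 ± 0.0577 to 124 ± 7.11 TPM (5.17, adjusted p = 4.86e-05). The water channel AQP1 rose from 4.77 ± 1.61 to 42.3 ± 13.8 TPM (2.90, adjusted p = 0.00196), KLF4 from 4.93 ± 0.657 to 19.7 ± 1.83 TPM (1.81, adjusted p = 0.00157), KLF2 from 65.5 ± 6.06 to 205 ± 32.7 TPM (1.63, adjusted p = 0.00157) and THBD from 95.02 ± 14.4 to 292 ± 12.8 TPM (1.62, adjusted p = 0.000248). CCM2L, the paralogue of CCM2, and HEG1 rose by 1.5 and 1.17, and TEK, the angiopoietin receptor, by 1.15. The potassium channel KCNN4 rose by 2.46, ABI3BP by 2.44, LCN6 by 2.59, the hypoxia-responsive NDRG1 by 0.88, the p53 target PHLDA3 by 0.59 and the membrane repair protein MYOF by 0.64. PTPN5 rose by 3.41, but its 2 values lay far apart (18.8 ± 19.2 TPM). EGR1, an immediate early transcription factor, fell from 5.24 ± 1.66 to 0.936 ± 0.173 TPM, the cyclin CCNA1 fell by 1.38, the protease inhibitor TFPI2 by 1.25, PYROXD2 by 1.36, MEX3A by 1.06, C16orf87 by 1.03 and RGCC by 1.00. SIGLEC11, SIGLEC16, TNXB and GTF2H2C, which have near-identical copies, and AC009244.1 also passed and are uncertain.

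In this comparison 127 genes rose and 23 fell of 13529 tested (1609 at unadjusted p under 0.05). Of 13 laminar-flow-induced genes 7 rose (8 adjusted over the list alone) and all 13 were positive (median 1.46, camera adjusted p = 9.4e-18, but adjusted p = 0.063 with an estimated correlation). The list of genes raised after CCM complex loss shares KLF2, KLF4, NOS3, THBD and AQP1 with it, so its result is not independent. Of 10 genes raised after CCM complex loss 6 rose (9 adjusted over the list alone; median 1.56, adjusted p = 8.32e-15, and adjusted p = 0.063 with an estimated correlation). Of 16 endothelial identity genes 1 rose (3 adjusted over the list alone; median 0.23, adjusted p = 8.33e-05, and adjusted p = 0.393 with an estimated correlation). The 16 cholesterol synthesis genes were all positive (median 0.26, 0 passed, 5 higher adjusted over the list alone; adjusted p = 8.83e-06, and adjusted p = 0.287 with an estimated correlation). The 11 mitochondrially encoded genes had a median of -0.32 (0 passed in either way; adjusted p = 0.0366, and adjusted p = 0.864 with an estimated correlation), and the library of guide C2 held the lowest mitochondrial share of this experiment, 4.46%. The count was 64 without guide C2, 66 without control guide B6 and 234 without guide F6, and 71 with quality weights, while 11 of the 29 named genes called here passed in all 12 cases, CCM2, PI16, AQP1, KLF2, KLF4 and THBD among them.

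TLNRD1 guides with control nucleofection raised several of the same genes. PI16 rose from 2.47 ± 0.0577 to 30.4 ± 7.24 TPM (3.16, adjusted p = 0.00171), THBD from 95.02 ± 14.4 to 238 ± 23.2 TPM (1.32, adjusted p = 0.0014), KLF2 from 65.5 ± 6.06 to 145 ± 25.2 TPM (1.12, adjusted p = 0.0252) and NOS3 from 91.9 ± 7.17 to 176 ± 13.6 TPM (0.93, adjusted p = 0.0222). KLF4 stood at 11.8 ± 2.65 and 4.93 ± 0.657 TPM (1.10, adjusted p = 0.0544). CRISPLD2 rose by 1.83, the phospholipase-like PLCXD3 by 1.77, the chloride channel ANO1 by 1.69, LYPD5 by 1.95, KIAA1211L by 1.68, TBC1D2 by 1.54 and the cytidine deaminase CDA by 1.43. CCM2L and HEG1 rose by 0.93 and 0.85, the plasminogen activator PLAT by 0.81, and the cholesterol synthesis enzymes MSMO1 and HMGCS1 by 0.57 and 0.56. Of the neighbours of TLNRD1, CFAP161 rose by 1.58 (adjusted p = 0.0138) and MESD from 40.1 ± 4.61 to 75.0 ± 3.97 TPM (0.89, adjusted p = 0.0138). TFPI2 fell by 1.55, GMFG by 0.79 and the endothelial lipase LIPG by 0.75. ASDURF, which overlaps another gene, and AC080038.1 are uncertain.

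In this comparison 43 genes rose and 5 fell (1217 at unadjusted p under 0.05). Of 13 laminar-flow-induced genes 4 rose (8 adjusted over the list alone) and all 13 were positive (median 0.93, adjusted p = 8.65e-13, but adjusted p = 0.139 with an estimated correlation). Of 10 genes raised after CCM complex loss 3 rose (6 higher and 1 lower adjusted over the list alone; median 1.02, adjusted p = 2.89e-09, and adjusted p = 0.139 with an estimated correlation), and of 16 cholesterol synthesis genes 2 rose, with all 16 positive (6 adjusted over the list alone; median 0.33, adjusted p = 1.88e-10, and adjusted p = 0.139 with an estimated correlation). In static culture the cholesterol synthesis median with TLNRD1 guides was -0.18, so its direction was opposite in the flow experiment. The 12 NF-kB inflammation genes had a median of -0.64 (0 passed in either way; adjusted p = 0.00195, and adjusted p = 0.649 with an estimated correlation). The count was 6 without guide B3, 16 without guide D12, 10 without control guide B6 and 90 without control guide D2, and only TLNRD1, PI16 and THBD of the 23 named genes called here passed in all 12 cases.

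The effects of CCM2 and TLNRD1 guides were then set side by side. With control nucleofection 35 of the 43 genes that rose with TLNRD1 guides also rose with CCM2 guides, where independent lists would share 0.404. Both comparisons use the same control libraries, which may account for part of the overlap. Across 13526 genes, which are not independent replicates, the log2 fold changes of the targets correlated at 0.602 (Spearman 0.546), but shared controls alone gave 0.5 in simulations. The covariance was 0.0786 against 0.0423 simulated, a difference of 0.0363. In static culture the correlation was 0.616 (0.498 simulated) and the covariance 0.0745 against 0.0568, a difference of 0.0177, or 0.0747 against 0.0379, a difference of 0.0368, without B6 under flow, which enters the simulated spread. Without single static libraries this correlation ran from 0.491 (TLNRD1 guide B3) to 0.732 (control guide B6). Leaving out a library also changes the correlation that shared controls alone give, which was simulated only with all static libraries. So this range does not measure similarity alone. Comparisons that share no library gave 0.316 for CCM2 in static culture with TLNRD1 after nucleofection, and 0.273 for the converse, where simulations gave at most 0.0482 and 0.0915. The 2 experiments correlated at 0.411 for CCM2 and at 0.182 for TLNRD1. All comparisons between the experiments set both sides against control guides B6 and D2. A trait of those control cells would enter both sides, and the simulations held no such trait. The 150 genes called for CCM2 after nucleofection, a list chosen after the data were seen, had a median of 0.79 in their own direction in static culture (142 in that direction, 94.7%, limma's fry, adjusted p = 0.0025 over 6 signatures), and the 48 genes called for TLNRD1 a median of 0.61 (45, 93.8%, fry adjusted p = 0.00711).

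The genes that changed with flow in control-guide cells, 1297 of which were tested in both experiments, were followed in CCM2-guide cells after control nucleofection, to set the effect of the guides beside that of flow. There they had a median of 0.14 on the log2 scale in the direction of flow, with 886 of them (68.3%) in that direction (fry adjusted p = 0.0115). In TLNRD1-guide cells the median was 0.022, with 700 (54%) in that direction (fry adjusted p = 0.475). Without D2 under flow the medians were 0.067, no longer past the threshold, and -0.047, and 1 fit of all 24 libraries gave 0.104 for CCM2-guide cells, likewise not past it. Without B6 under flow they were 0.149 and 0.0649 over 1228 genes, with 865 (70.4%) and 745 (60.7%) in that direction (fry adjusted p = 0.00549 and 0.12). Without the static library of B6 they were 0.263 and 0.11, and there the TLNRD1 signature passed the threshold, the only 1 of 24 such cases in which it did. Without the control nucleofection library of guide C2 the CCM2 median was 0.0791, and without that of guide B3 the TLNRD1 median was 0.

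**Figure D4:**
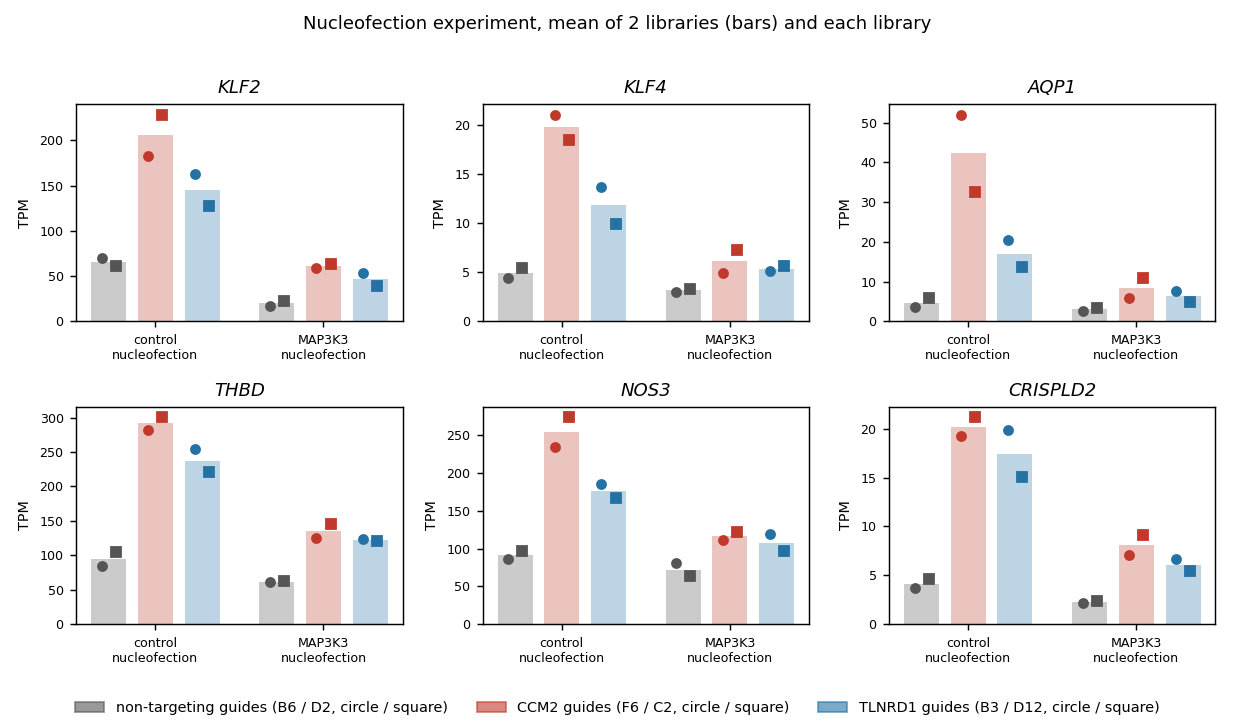
TPM of KLF2, KLF4, AQP1, THBD, NOS3 and CRISPLD2 in the 12 libraries of the nucleofection experiment (circles and squares for the 2 guides of a target), with bars at the mean of the 2 libraries of each group, for control and MAP3K3 nucleofection. KLF2 averaged 65.5, 205 and 145 TPM with control, CCM2 and TLNRD1 guides after control nucleofection, and 19.8, 61.2 and 46.3 TPM after MAP3K3 nucleofection.

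MAP3K3 guides were compared with non-targeting guides in each background, to follow the same genes when MEKK3 is targeted as well. No arm held guides that cut another locus, so loss of MAP3K3 and cutting by Cas9 cannot be told apart in these comparisons. KLF2 fell in all 3, from 65.5 ± 6.06 to 19.8 ± 3.72 TPM in control-guide cells (-1.68, adjusted p = 0.0064), from 205 ± 32.7 to 61.2 ± 3.39 TPM in CCM2-guide cells (-1.72, adjusted p = 0.00506) and from 145 ± 25.2 to 46.3 ± 9.72 TPM in TLNRD1-guide cells (-1.63, adjusted p = 0.0208). KLF4 fell from 19.7 ± 1.83 to 6.10 ± 1.59 TPM in CCM2-guide cells (-1.56, adjusted p = 0.0119) and stood at -0.99 (adjusted p = 0.24) in TLNRD1-guide and -0.51 (adjusted p = 0.963) in control-guide cells. In CCM2-guide cells AQP1 fell by 2.21, NOS3 from 255 ± 27.6 to 117 ± 8.13 TPM (-1.12, adjusted p = 0.0119), THBD by 1.11, the small GTPase RHOB by 1.04, CRISPLD2 by 1.23, the hedgehog ligand DHH by 1.17 and the chaperone HSPA12B by 1.09. In TLNRD1-guide cells THBD fell from 238 ± 23.2 to 122 ± 1.66 TPM (-0.95, adjusted p = 0.0271), RHOB by 0.92 and CRISPLD2 by 1.38. AL500527.2, AC069257.2, AC099677.1, AC073896.1, SULT1A4, which has a near-identical copy, and MTRNR2L2, which resembles the mitochondrial 16S rRNA gene, also passed and are uncertain.

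The counts were 3 higher and 1 lower gene in control-guide cells, 3 and 13 in CCM2-guide cells and 0 and 7 in TLNRD1-guide cells (692, 1108 and 749 at unadjusted p under 0.05). Of 13 laminar-flow-induced genes 5 fell in CCM2-guide cells (8 adjusted over the list alone), with all 13 negative (median -1.11, camera adjusted p = 9.31e-18, but adjusted p = 0.0696 with an estimated correlation). In TLNRD1-guide cells 2 of the 13 fell (8 adjusted over the list alone; median -0.72, adjusted p = 4.42e-12, and adjusted p = 0.141 with an estimated correlation), and in control-guide cells 1 (2 adjusted over the list alone; median -0.35, adjusted p = 0.000255, and adjusted p = 0.411 with an estimated correlation). In CCM2-guide cells the 11 mitochondrially encoded genes were all positive (median 0.48, 0 passed in either way; adjusted p = 0.00109, and adjusted p = 0.637 with an estimated correlation), set against a control arm with the C2 library and its mitochondrial share of 4.46%. Of 3 epithelial markers there 0 passed and 2 were lower adjusted over the list alone (median -0.65, adjusted p = 0.000693, and adjusted p = 0.341 with an estimated correlation). The 10 laminar-flow-repressed genes had medians of 0.62 and 0.57 in CCM2-guide and TLNRD1-guide cells (0 passed, 3 higher adjusted over the list alone in each; adjusted p = 0.000107 and 1.81e-05, and adjusted p = 0.297 and 0.141 with an estimated correlation). The 16 p53 targets were positive in 16, 14 and 15 cases in control-guide, CCM2-guide and TLNRD1-guide cells (medians 0.27, 0.19 and 0.30; 0 passed, 6, 2 and 1 higher adjusted over the list alone; adjusted p = 2.24e-11, 0.0178 and 4.09e-09, and adjusted p = 0.353, 0.637 and 0.141 with an estimated correlation). The 21 cell cycle genes were all negative in control-guide cells (median -0.39, 0 passed, 2 lower adjusted over the list alone; adjusted p = 2.29e-13, and adjusted p = 0.411 with an estimated correlation). In control-guide cells the count was 0 without D2 of the control arm (1283 at unadjusted p under 0.05), or without B6 (549) or D2 (660) of the MAP3K3 arm. In CCM2-guide cells it was 0 without C2 (808) and 29 without F6 of the control arm, and 9 without C2 and 2 without F6 of the MAP3K3 arm. In TLNRD1-guide cells it was 0 without D12 (652) or B3 (564) of the MAP3K3 arm, 2 and 1 without D12 and B3 of the control arm, 3 without either control-guide library of the MAP3K3 arm and 14 without either CCM2 library of the control arm; KLF2 passed in 8, 10 and 9 of 12 cases, and of the 4, 12 and 5 named genes called in the 3 backgrounds 0 passed in all 12 cases.

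Whether MAP3K3 guides acted differently in CCM2-guide or TLNRD1-guide cells than in control-guide cells was tested as an interaction. KLF2 differed by -0.04 (adjusted p = 1) for CCM2 and 0.06 (adjusted p = 1) for TLNRD1, and KLF4 by -1.06 (adjusted p = 1) and -0.49 (adjusted p = 1). The uncertain AC099677.1 passed in both (-5.09, adjusted p = 0.0017, and -5.02, adjusted p = 0.00197), and MTRNR2L2 for CCM2 (3.77, adjusted p = 0.0419). The unadjusted p was under 0.05 for 597 and 336 genes, and simulated differences for the CCM2 interaction were recovered in 64% of cases at 2-fold and 98% at 4-fold. Of 13 laminar-flow-induced genes 0 passed for CCM2, 5 were lower adjusted over the list alone and all 13 were negative (median -0.60, adjusted p = 1.33e-08, but adjusted p = 0.38 with an estimated correlation). The CCM2 count of 2 was 1 without any of 8 single libraries, both of the CCM2 MAP3K3 arm among them, and the TLNRD1 count of 1 was 2 or 3 without any of 8, with 3 without B6 of the control arm, D2 of the MAP3K3 arm, or the D12 or B3 library of the TLNRD1 control arm. The planned signature of CCM2 knockdown from static culture held 1 gene, AC000041.1 (median 1.5, fry adjusted p = 0.432). That of TLNRD1 held 2, TLNRD1 itself and its neighbour MESD (median -0.14, fry adjusted p = 0.432). It could therefore not show whether MAP3K3 guides changed other effects of TLNRD1 knockdown. Without B6 under flow the CCM2 signature held 147 genes, whose median in the direction of knockdown was 0.77 with control nucleofection and 0.41 with MAP3K3 guides, an interaction median of -0.34 (fry adjusted p = 0.05). For guide F6 these medians were 0.68 and 0.34, and for C2 0.87 and 0.50.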

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

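Of the tests below, those of cycling cells, of DNA cutting and of other neighbouring genes were chosen only after the result was seen, as was leaving out the library of guide B6 under flow.

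The results listed here were picked out because a test of the difference itself, an interaction term, passed for a gene or, with a preset correlation, for a gene list. For CCM2 by flow the gene was RNA5SP385 (3.09), and for TLNRD1 by flow the same gene (6.19), which is a 5S rRNA pseudogene and uncertain. For CCM2 by flow the median difference was -0.56 for laminar-flow-induced genes, -0.45 for genes raised after CCM complex loss, -0.68 for the ER stress and amino acid response and 1.43 for mitochondrially encoded genes. For TLNRD1 by flow it was -0.42 for laminar-flow-induced genes, 0.35 for cholesterol synthesis, 1.40 for mitochondrially encoded genes and -0.57 for epithelial markers. The control group in both sets held the B6 library, with 1.81% of TPM in mitochondrially encoded genes. Without that library the medians for CCM2 by flow, in the same order, were -0.70, -0.53, -0.10 and 0.00194, and the ER stress and mitochondrial lists were no longer called (camera adjusted p = 0.528 and 0.821). For TLNRD1 by flow they were -0.55, 0.65, -0.0955 and -0.33, so the mitochondrial difference changed sign, and the epithelial list was no longer called (adjusted p = 0.168). The ER stress and mitochondrial differences thus depend on that 1 library. For CCM2 by MAP3K3 the genes were AC099677.1 (-5.09) and MTRNR2L2 (3.77), and for TLNRD1 by MAP3K3 AC099677.1 (-5.02). For CCM2 by MAP3K3 the median difference was -0.60 for laminar-flow-induced genes, -0.42 for genes raised after CCM complex loss, -0.098 for endothelial identity, -0.22 for coagulation and fibrinolysis, 0.48 for NF-kB inflammation, -0.12 for p53 targets and 0.38 for the cell cycle. For TLNRD1 by MAP3K3 it was -0.35 for laminar-flow-induced genes, -0.27 for genes raised after CCM complex loss and 0.30 for the cell cycle. With an estimated correlation no list passed in any of the 4 interactions, and the smallest adjusted p values were 0.986, 0.889, 0.38 and 0.917 in the order given.

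The library of guide B6 under flow stood apart from the other 11, with a median correlation of 0.908 to them. Its deviation from the rest rose with GC content (Spearman 0.397, against -0.166 to 0.107 in the others), but removing a GC trend from each library left the median correlation at 0.917, below the lowest pair of the others at 0.956. Over 11011 protein-coding genes with no pseudogene named after them it was 0.905, and without the mitochondrially encoded genes 0.907, against lowest pairs of 0.952 and 0.953, so none of GC content, reads shared with pseudogenes or the low mitochondrial share accounts for the whole difference. Among its 16 genes at 10 times the highest other library or more, 11 were pseudogenes, against 1313 of all 13920 tested. Among its 15 genes at 1/10 of the lowest other library or less, 9 were pseudogenes. Pseudogenes were thus frequent among the extreme genes in both directions. No biological explanation was tested, since the other control library under flow had the same treatment.

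The p53 targets were called higher as a list with MAP3K3 guides in each background, but only with the preset correlation, and 0 of the 16 members passed. A shift in the scaling of libraries would leave the list no higher than all genes. Its median exceeded that of all genes by at least 0.164 over 3 backgrounds and 2 scalings. That lowest value came from median-ratio scaling, which moves all genes of a library alike and so could hardly change the excess. With quantile normalization, which could change it, the excess was 0.285, 0.185 and 0.289 in control-guide, CCM2-guide and TLNRD1-guide cells. Fewer cycling cells cannot be told apart as a source. The cell cycle list was lower in control-guide cells and in TLNRD1-guide cells (medians -0.39 and -0.10). In TLNRD1-guide cells its median was 0.266 of that in control-guide cells while the p53 median was 1.14 of it, but this smaller fall was not beyond its spread with an estimated correlation (adjusted p = 0.917). In CCM2-guide cells the cell cycle list had a median of -0.0231 with 9 of 21 genes positive, 0.06 of that in control-guide cells, while the p53 median was 0.723 of it with 14 of 16 positive, which goes against this explanation, but there too the smaller fall was not beyond its spread (adjusted p = 0.803). Cutting of DNA by Cas9 may raise p53 targets whatever the locus, and it cannot be told apart from loss of MAP3K3, because 0 arms held guides that cut another locus. The list's call was lost with an estimated correlation, where the smallest adjusted p of the 3 backgrounds was 0.141.

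MESD was higher with TLNRD1 guides in both experiments, by 1.93 and 0.89. Reads shared between the genes are argued against by their transcripts, which have 0 stretches of 31 bases in common. A local effect of the guides on neighbouring genes cannot be told apart from an effect of TLNRD1 loss. Besides MESD, 1 gene within 500 kb, CFAP161, rose in a local search of 6 tested neighbours, at percentile 99.75 of all genes' log2 fold changes after nucleofection. But CFAP161 also stood at 7.97 (F6) and 9.42 TPM (C2) with CCM2 guides after control nucleofection, against 4.34 (B6) and 4.54 TPM (D2). It was lower with MAP3K3 guides than with control nucleofection in each background. Its higher values were thus not limited to TLNRD1 guides. In static culture its values with CCM2 and control guides overlapped. Also, 1 of 9 tested neighbours of CCM2, OGDH, rose with CCM2 guides from 290408 bases away (0.55, adjusted p = 0.0237), at percentile 94.7. Of the other tested neighbours of TLNRD1, IL16 and CEMIP stood at 1.05 and 0.99 in static culture and at 0.98 and 0.78 after nucleofection, while ABHD17C stood at -0.48 and -0.17 and STARD5 at 0.03 and -0.46, and none of these 4 passed. In the same order of conditions, percentiles were 99.15 and 98.8 for IL16 and 99.07 and 97.91 for CEMIP. They were 4.92 and 22.11 for ABHD17C and 60.76 and 5.78 for STARD5. The highest percentile of a CCM2 neighbour was 95.04, for ZMIZ2 after nucleofection.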

How the results depend on the processing

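Leaving out the library of guide B6 under flow, quality weights, and the replicate block with that library left out were chosen only after the data were seen, as were the nucleofection signatures; the other alternatives were planned. Quantile normalization and median-ratio scaling kept the total of higher and lower genes within 1.5 times of its value, but not each direction (with flow in TLNRD1-guide cells 333 higher genes became 195 and 225, and 76 lower genes 110 and 123), and every signature on its side of the threshold. Causes were not tested except where fewer libraries or more genes tested make the change. Depth is unknown, so no limit from it could be set.

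With a pseudocount of 0.1 the counts were 1 for CCM2 guides in static culture, 1 for CCM2 guides under flow, 2 for MAP3K3 guides in control-guide cells, 1 for CCM2 by MAP3K3 and 2 for TLNRD1 by MAP3K3, and the similarity of CCM2 and TLNRD1 effects was 0.563. With no filter on low values the counts were 856, 139 and 247 for flow in control-guide, CCM2-guide and TLNRD1-guide cells, 9 and 12 for CCM2 and TLNRD1 guides in static culture, 17 and 25 under flow, 12 and 2 for their interactions with flow, 12 for CCM2 against TLNRD1 guides, 31, 25 and 17 for MAP3K3 guides in control-guide, CCM2-guide and TLNRD1-guide cells, and 8 and 23 for the interactions with MAP3K3; the CCM2 and TLNRD1 signatures under MAP3K3 guides were 0 and 0.038. One fit of all libraries gave 3308, 799 and 1144 for flow, 72 and 5 for static CCM2 and TLNRD1 guides, 1 and 1 under flow, 31 for TLNRD1 guides with control nucleofection, 2, 7 and 1 for MAP3K3 guides and 1 for CCM2 by MAP3K3; its CCM2 signature was -0.44, past the threshold, and its flow signatures 0.104, no longer past it, and -0.00299.

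The labels share guides between groups but name no shared culture or batch. The differences between the guides of a target correlated across conditions at 0.0317, 0.0269 and 0.0525 in the flow experiment (non-targeting, CCM2, TLNRD1) and at 0.00188, -0.028 and 0.0538 in the nucleofection experiment, so pairing was not assumed. With the replicate block the counts were 657, 66 and 70 for flow, 0 for CCM2 by flow (limma, 604 at unadjusted p under 0.05), and 1 each for MAP3K3 guides in control-guide and TLNRD1-guide cells and for CCM2 by MAP3K3. With the block and without B6 under flow they were 297, 735 and 1290 for flow, 0 for CCM2 by flow (682 at unadjusted p under 0.05) and 2 for TLNRD1 by flow.

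Without B6 under flow the counts were 1363 and 1919 for flow in CCM2-guide and TLNRD1-guide cells, 149 and 6 for CCM2 and TLNRD1 guides in static culture, 0 for CCM2 guides under flow (794 at unadjusted p under 0.05) and 2 for CCM2 by flow; the signatures under MAP3K3 guides were -0.337, past the unadjusted threshold, and 0.0432, and MT-CO1 turned from -0.962 to 0.406 with flow in control-guide cells (adjusted p = 0.00645). With quality weights, which are equal for both libraries of a group and so do not single out B6, the counts were 17, 1417 and 1840 for flow, 140 and 9 in static culture, 0 and 0 under flow (628 and 393 at unadjusted p under 0.05), 0 for CCM2 by flow (549), 71 for CCM2 guides with control nucleofection, 30 for MAP3K3 guides in TLNRD1-guide cells and 1 for CCM2 by MAP3K3, and the signatures -0.37 and 0.0512. The 114 list calls of the fits with all libraries became 0 with an estimated correlation. No scaling turned the sign of the median of a list called in those fits.

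Without each library in turn the ranges were 100 to 6154, 13 to 1363 and 40 to 1929 for flow, 0 to 149 and 0 to 6 for CCM2 and TLNRD1 guides in static culture, 0 to 5174 and 2 to 4827 under flow, 0 to 3457 and 1 to 3247 for the interactions with flow, 0 to 3 for CCM2 against TLNRD1 guides, 64 to 234 and 6 to 90 with control nucleofection, 0 to 6, 0 to 29 and 0 to 14 for MAP3K3 guides, and 1 to 2 and 1 to 3 for the interactions with MAP3K3. The CCM2 and TLNRD1 signatures ran from -0.885 to 2.07 and -1.5 to 0.0432, the flow signatures from 0.0668 to 0.263 and -0.0471 to 0.11, the nucleofection signatures in static culture from 0.488 to 1.05 and 0.319 to 0.775, and the similarity from 0.491 to 0.732. The similarity that shared controls alone give was not simulated without single static libraries. MT-CO1 with flow in control-guide cells ran from -2.33 (without D2 under flow) to 0.406, and PGD in TLNRD1 by flow from -0.637 (adjusted p = 0.0219, without D2 under flow) to 0.694. Of 1197 named gene results 1136 stayed on their side with the block, 60 were lost and 1 gained.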

Other observations

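Nothing in this part was tested beyond the comparisons already described, and the genes and lists given here come from the lists chosen in advance.

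Of 19 targets of YAP and TAZ, the mechanosensitive coactivators, 3 rose with flow in control-guide cells (ANKRD1, CRIM1 by 0.89 and CCDC80 by 0.72), 1 in CCM2-guide cells (CCDC80 by 1.23) and 2 in TLNRD1-guide cells (CCDC80 by 1.08 and CRIM1 by 0.80), or 7, 7 and 10 adjusted over the list alone. Their medians were 0.62, 0.49 and 0.53 (camera adjusted p = 0.00239, 5.57e-05 and 0.000284, but adjusted p = 0.287, 0.15 and 0.2 with an estimated correlation). The 20 actin cytoskeleton and contractility genes had medians of -0.22 and -0.20 with flow in CCM2-guide and TLNRD1-guide cells, where 1 (TAGLN) and 0 fell (3 and 2 adjusted over the list alone; adjusted p = 5.57e-05 and 0.000383, and adjusted p = 0.266 and 0.331 with an estimated correlation). The lymphatic genes fell in 1 and 2 of 2 cases in those cells (2 and 2 adjusted over the list alone; medians -1.32 and -1.66, adjusted p = 0.00158 and 0.000378, and adjusted p = 0.15 and 0.105 with an estimated correlation). In control-guide cells COL8A1 and NID2 of the matrix list rose with flow by 2.05 and 1.78, the arterial transcription factor SOX17 by 1.42 and the venous receptor APLNR by 2.80, the junction protein JUP fell by 1.69, and OAS2 of the interferon response fell by 1.29. These are single members of lists that were not called there: of 15 matrix, 7 arterial, 5 venous, 12 junction and 12 interferon genes, 2, 1, 1, 2 and 0 rose and 0, 2, 0, 2 and 1 fell, as many as adjusted over the list alone except for 3 higher matrix genes (adjusted p = 0.25, 0.0532, 0.743, 0.408 and 0.932, and adjusted p = 0.757, 0.287, 0.88, 0.705 and 0.966 with an estimated correlation).

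Markers of other cell types were measured in each comparison. The epithelial members with the highest means, KRT18 and KRT19, stood at 846 ± 48.3 and 225 ± 91.7 TPM in control-guide cells under flow. The leukocyte markers CD68 and CD14 stood at 35.8 ± 11.1 and 10.0 ± 7.32 TPM there. Control-guide cells thus expressed these genes, and a change in these lists does not by itself show cells of another type. Of 4 epithelial markers tested in static culture 0 passed with CCM2 guides, 2 were higher adjusted over the list alone (median 0.63, adjusted p = 0.00361, and adjusted p = 0.139 with an estimated correlation), and of 3 tested after nucleofection 0 passed with MAP3K3 guides in control-guide cells and 3 were lower adjusted over the list alone (median -0.43, adjusted p = 0.00155, and adjusted p = 0.411 with an estimated correlation). The list was also called with TLNRD1 guides in static culture (median 0.30, 1 higher adjusted over the list alone; adjusted p = 0.012, and adjusted p = 0.256 with an estimated correlation). After control nucleofection it was called with CCM2 and TLNRD1 guides (medians 0.62 and 0.50, 3 and 2 higher adjusted over the list alone; adjusted p = 0.00673 and 0.0202, and adjusted p = 0.393 and 0.638 with an estimated correlation). With MAP3K3 guides it was called in CCM2-guide and TLNRD1-guide cells too (medians -0.65 and -0.58, 2 lower adjusted over the list alone in each; adjusted p = 0.000693 and 0.00016, and adjusted p = 0.341 and 0.158 with an estimated correlation). In each of these 7 comparisons 0 members passed and the median of the laminar-flow-induced genes had the same sign. The 2 leukocyte markers tested had medians of 0.70 and 0.85 with CCM2 guides in static culture and after nucleofection (0 passed, 1 higher adjusted over the list alone in each; adjusted p = 0.0364 and 0.0366, and adjusted p = 0.271 and 0.287 with an estimated correlation). With MAP3K3 guides the 16 cholesterol synthesis genes were negative in 16 cases in TLNRD1-guide cells (median -0.18, 0 passed in either way; adjusted p = 3.82e-07, and adjusted p = 0.141 with an estimated correlation). In the same cells the 11 BMP and TGF-beta response genes had a median of 0.29 (0 passed, 2 higher adjusted over the list alone; adjusted p = 0.000481, and adjusted p = 0.198 with an estimated correlation). In the fits with all libraries, 25 of the 33 lists were called in at least 1 comparison with the preset correlation, 114 calls in all. There 8 were called in none: the Notch pathway, mesenchymal transition, angiogenic tip cells, hypoxia and glycolysis, immediate early genes, heat shock, smooth muscle markers and fibroblast markers. Fits without B6 under flow are not in these counts.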
